A study of Mus musculus with 29 samples.

How the data were processed

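Small RNA was sequenced from the gastrocnemius, a calf muscle, of 29 male BALB/c mice about 2 months old. Per the labels' protocols, mice were assigned at random to 5 groups for 6 weeks. The control group received phosphate-buffered saline by intraperitoneal injection (n = 5) and the lactate group sodium L-lactate at 500 mg per kg (n = 6). The HIIT group ran treadmill high-intensity intervals (n = 6). The inhibitor group received AR-C155858 (n = 6), which blocks the monocarboxylate transporters MCT1 and MCT2 that carry lactate across membranes, and the HIIT + inhibitor group received both (n = 6). Muscle was taken 48 h after the last session. Total RNA from 20 to 30 mg of tissue was isolated with a column kit, and 100 ng went into libraries made with the NEXTFLEX Small RNA-Seq Kit v4 with 17 PCR cycles, sequenced as single-end reads of 75 bp on a NovaSeq X Plus, per the labels' protocols. All libraries carry 1 batch label, and no date or lane was given in the sources used here.

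The authors deposited 1 table of whole-number read counts per mature miRNA, which was used as deposited. FastQC, MultiQC and Bowtie, without versions, and the genome build GRCm39 are named per the submitters' processing notes. The trimming, the counting program, the miRNA annotation release, any use of molecular identifiers and the handling of reads that match several miRNAs are not given in the sources used here. The table held 1927 mature miRNAs, of which 883 had no count in any library. There were 35 entries that join the names of several miRNAs, such as miR-133a-3p/133b-3p, and these are reported under the joint name, since their reads were not separated. Near-identical family members (let-7, miR-29, miR-30) can share reads, so values of single members are uncertain to that extent. No name occurred more than once. The smallest count above 0 was 2 and no count of 1 occurred. There were 147 zeros in 34 tested miRNAs where the other libraries led to an expectation of at least 20 counts. A 0 in this table is therefore not read as a limit of detection, and miRNAs at 0 throughout a group are given as listed at 0 with no fold.

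Total counts per library ran from 2.24 to 7.24 M (M for mega). Counts of PCR-amplified reads are not independent molecules, so the 95% Wilson interval printed beside a share of 1 library covers counting error only. Replicate libraries of a group differed from each other far beyond counting noise, with a chi-square per degree of freedom of at least 100 in each pair, and each library was counted as 1 mouse.

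Differences between groups were tested with edgeR 4.0.16 in R 4.3.3. Counts were scaled with TMM factors, and miRNAs were kept with filterByExpr by group (minimum count 10, minimum total 15, minimum proportion 0.7), which left 481 tested miRNAs holding at least 99.98% of each library's counts. Another 563 had a count but were not tested. The quasi-likelihood test was fitted to all 29 libraries with 1 coefficient per group, so that the groups shared 1 estimate of the spread. It was two-sided. P-values were adjusted with the Benjamini-Hochberg method over the 481 miRNAs within each of 8 comparisons and of 1 test for any difference among the 5 groups, with a threshold of 0.05. Unless another setting is named, passing and not passing of single miRNAs refer to this fit, called the main edgeR fit. Changes are given as log2 fold changes with their standard error, computed from the fold change and its F statistic. Levels are TMM-normalized CPM, as mean ± SD. A number such as 6 of 6 gives how many libraries of the first group lay on the stated side of the mean of the second.

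miRNAs named in the text follow a rule. In each comparison they are the 10 with the smallest adjusted p among those that rose and the 10 among those that fell. Where fewer than 10 passed in all, the 10 with the smallest unadjusted p are named as not passing. The tested muscle-enriched miRNAs (myomiRs) and the 4 members with the smallest p of each list that passed are named as well. There were 22 lists of miRNAs: myomiRs, exercise-associated miRNAs, reported regulators of DNA methyltransferases, TET enzymes or EZH2, markers of endothelium, smooth muscle, red cells, leukocytes, nerve, epithelium, connective tissue and liver, miRNAs of hypoxia and inflammation, the let-7, miR-30, miR-29, miR-34/449, miR-181 and miR-15/16 families, the miR-17-92 and miR-23/27/24 clusters with their paralogs, and the imprinted Dlk1-Dio3 cluster. The 18 lists with at least 3 tested members were tested with camera in limma 3.58.1, which compares a list with all other tested miRNAs, at a preset correlation of 0.01 and two-sided, with adjustment over the 18 lists. Camera with an estimated correlation called no list in any comparison (smallest adjusted p 0.105), so each list call below holds only at the preset correlation. The comparisons, tests, lists, naming rule and most alternatives were fixed before the data were examined.

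Each fit was tested on simulated counts drawn from the means and library sizes of these libraries, with 67 miRNAs changed 1.5-fold, 67 changed 2-fold and 66 changed 4-fold among the 481. For the comparison of the inhibitor group with control, edgeR recovered 19.4% of 1.5-fold, 58.2% of 2-fold and 74.2% of 4-fold changes. For lactate against control the shares were 25.4%, 64.2% and 89.4%, for HIIT against control 11.9%, 44.8% and 75.8%, and for the interaction 5.97%, 25.4% and 69.7%. With so many miRNAs changed at once the adjusted threshold is more lenient than with few. These shares can therefore overstate the recovery in the real comparisons, where few or no miRNAs passed.

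Library totals, the number of miRNAs with a count and the shares of the most abundant miRNAs were compared with exact two-sided permutation tests, adjusted over the 4 treated groups. With 5 against 6 mice there are 462 splits, and the smallest p is 0.00216. Correlations of fold changes between comparisons that share the control libraries were set beside 100 simulations of unchanged groups and beside splits of the controls into separate parts. The simulations drew each miRNA independently, and the split controls were simulated in only a part of them. The alternatives were RLE scaling, total counts with no scaling factor, no filter, a mean of at least 50 CPM, DESeq2 1.42.0, limma voom with quality weights, a robust fit, a fit of only the groups compared, the replicate number as a block, and each library left out in turn. Added after the data were seen were thinning of every library to the smallest total, a correction for the GC content of the hairpin arm, removal of the miRNAs with improbable zeros, another pair of fold-change comparisons, and an exact permutation test of list scores per library. The score of a list is the mean over its members of the log2 CPM of a library (prior count 2), each member centered on its mean over all libraries. The mouse genome at hand was GRCm38, so it served only for the GC content of hairpin arms, found for 460 of the 481 miRNAs, and no coordinates are given.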

Results

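Counts of mature miRNAs were obtained from the gastrocnemius of 29 mice in 5 groups after 6 weeks of lactate injection, high-intensity interval training (HIIT), an inhibitor of the lactate transporters MCT1 and MCT2, training with the inhibitor, or saline. Mean totals, with M for mega, were 5.35 ± 0.76 M counts in control (SD, n = 5), 4.94 ± 1.34 M with lactate, 5.13 ± 0.71 M with HIIT and 5.16 ± 1.14 M with HIIT + inhibitor (n = 6 each). The inhibitor libraries were shallower, at 3.04 ± 0.58 M (n = 6), a difference from control of -2.31 M (exact permutation p = 0.00216, the smallest of 462 splits; adjusted p = 0.00866). They also listed fewer miRNAs, 497.3 ± 17.9 against 550 ± 25.1 in control (n = 6 and n = 5, exact permutation p = 0.00216, adjusted p = 0.00866). miR-1a-3p, the most abundant muscle miRNA, led in 28 of the 29 libraries, and in the remaining one miR-133a-3p/133b-3p led. The 10 most abundant miRNAs held 69.3% ± 3.21 of the counts (SD, 29 libraries). For the shares of the most abundant miRNA and of the first 10, no treated group passed against control (lowest adjusted exact permutation p = 0.268). The most abundant miRNA held 20.8% ± 5.52 with lactate and 21.6% ± 6.75 with the inhibitor, against 28.8% ± 7.87 in control. It held 28.0% ± 4.79 with HIIT and 32.6% ± 6.40 with HIIT + inhibitor. Mean TMM factors were 0.92 in control, 1.12 with lactate, 0.97 with HIIT, 1.09 with the inhibitor and 0.91 with HIIT + inhibitor. The test for any difference among the 5 groups passed for 65 of 481 miRNAs (139 at an unadjusted p under 0.05), led by miR-409-5p, miR-501-3p and miR-127-3p, each with an adjusted p of 0.000101. Normalized miR-409-5p was 50.7 ± 16.7 CPM in control, 77.0 ± 57.9 with lactate, 19.6 ± 1.80 with HIIT, 126 ± 17.1 with the inhibitor and 43.6 ± 8.0 with HIIT + inhibitor.

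Lactate against control asked what repeated lactate without exercise did to muscle miRNAs. A single miRNA passed. miR-20a-5p, a member of the proliferation-linked miR-17-92 cluster, fell from 152 ± 20.2 CPM (n = 5) to 93.5 ± 19.1 CPM (n = 6), a log2 change of -0.70 ± 0.15 (SE, adjusted p = 0.0339) with 6 of 6 lactate mice below the control mean. Its cluster and the let-7 family were lower as lists, as were nerve-enriched miRNAs and miRNAs reported to target DNA methyltransferases, TET enzymes or EZH2. Members of the imprinted Dlk1-Dio3 cluster were higher as a list.

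Of the miR-17-92 list, 8 of 10 tested members were below control (median log2 change -0.57, camera adjusted p = 0.00203, adjusted p = 0.287 with an estimated correlation). 1 fell over all miRNAs and 3 fell adjusted over the list alone. miR-25-3p (-0.45 ± 0.12), miR-106b-5p (-0.75 ± 0.21) and miR-17-5p (-0.37 ± 0.15) did not pass. All 12 tested DNA methylation and Polycomb regulators were below control (median -0.38, adjusted p = 0.00203, adjusted p = 0.287 with an estimated correlation), none past the threshold over all miRNAs and 2 adjusted over the list alone. The lowest p among them were those of miR-26b-5p (-0.65 ± 0.16), miR-152-3p (-0.65 ± 0.19), which targets DNMT1, miR-101a-3p/101b-3p/101c (-0.69 ± 0.28), which targets EZH2, and miR-148a-3p (-0.45 ± 0.22). The 6 neural miRNAs were all below control (median -0.96, adjusted p = 0.00203, adjusted p = 0.287 with an estimated correlation), 2 of them adjusted over the list alone and 0 over all. Examples were miR-9-3p (-1.96 ± 0.60), miR-9-5p (-1.79 ± 0.57), miR-124-3p (-1.37 ± 0.66) and miR-138-5p (-0.54 ± 0.24). The let-7 list had 7 of 9 members below control (median -0.28, adjusted p = 0.0113, adjusted p = 0.287 with an estimated correlation), 3 adjusted over the list alone and 0 over all. These included let-7g-5p (-0.47 ± 0.15), let-7f-5p (-0.52 ± 0.18), miR-98-5p (-0.51 ± 0.18) and let-7i-5p (-0.28 ± 0.12). In the Dlk1-Dio3 list 37 of 48 members were above control (median 0.41, adjusted p = 0.0113, adjusted p = 0.350 with an estimated correlation), with 0 adjusted over the list alone and 0 over all. The lactate mice were split, with cluster scores of 0.38, 1.08 and 0.88 in lactate 1 to 3 and -0.01, -0.54 and -0.47 in lactate 4 to 6, against a control mean of -0.08. The exact permutation test of the score did not pass (p = 0.364). miR-337-5p (0.93 ± 0.31), miR-412-5p (3.12 ± 1.16), miR-127-3p (0.66 ± 0.25) and miR-382-5p (0.69 ± 0.28) had the lowest p.

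The other miRNAs with the smallest unadjusted p in lactate against control did not pass in the main edgeR fit. They were miR-500-3p (0.78 ± 0.19, adjusted p = 0.0688), miR-615-3p (0.93 ± 0.24, adjusted p = 0.0731), miR-324-5p (0.59 ± 0.16), miR-1306-5p (0.71 ± 0.21) and miR-137-3p (-2.72 ± 0.82). Among the myomiRs, which muscle expresses far above other tissues, none passed with edgeR. miR-1a-3p differed by -0.76 ± 0.25 (adjusted p = 0.114, limma voom adjusted p = 0.0119), miR-499-5p by -1.12 ± 0.52, miR-208b-3p by -0.69 ± 0.59, miR-486a-5p/486b-5p by 0.18 ± 0.20, miR-133a-3p/133b-3p by 0.21 ± 0.27 and miR-206-3p by -0.22 ± 0.37. The count of 1 was 0 with a fit of only the groups compared, 28 with DESeq2, 50 with limma voom and 28 with total counts, where all 28 were higher and the median of all miRNAs stood at 0.28. The call of miR-20a-5p ended with total counts (-0.43, adjusted p = 0.0688), no filter (adjusted p = 0.111), only the groups compared (adjusted p = 0.0934) and thinning to 1 depth (adjusted p = 0.0623). It also ended without any 1 of control 1, 3, 4 or 5, lactate 1 or 3, HIIT 1 or HIIT + inhibitor 4 (adjusted p 0.0524 to 0.106). The let-7 list call ended with total counts (adjusted p = 0.299), without the miRNAs with an improbable zero (0.0622) and without control 5 or lactate 2 or 6 (adjusted p 0.0748 to 0.117). That of the Dlk1-Dio3 list ended with total counts (adjusted p = 0.0780) and without control 2 or 5 or lactate 2 or 3 (adjusted p 0.0728 to 0.210). The count was 23 without lactate 6 and 2 to 7 without any 1 of control 2, lactate 2, 4 or 5, HIIT 2, 3 or 4, inhibitor 1 to 4 or HIIT + inhibitor 3.

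HIIT against control asked what training did. None of the 481 miRNAs passed with edgeR, while 48 had an unadjusted p under 0.05, and DESeq2 called 11 and limma voom 8. As lists, nerve-enriched miRNAs and the Dlk1-Dio3 cluster were lower in trained mice. The lowest p was that of miR-124-3p, the main neuronal miRNA. It was at 74.1 ± 68.7 CPM with HIIT (n = 6) against 594 ± 401 CPM in control (n = 5), a log2 difference of -3.0 ± 0.69 that missed the threshold (adjusted p = 0.0565) with 6 of 6 trained mice below the control mean. It passed with 8 of the other settings (adjusted p 0.00150 to 0.0480), DESeq2 (0.00263) and limma voom (0.0141) among them. The 6 neural miRNAs had a median log2 change of -1.91 (camera adjusted p = 4.98e-06, adjusted p = 0.105 with an estimated correlation), with 3 lower adjusted over the list alone and 0 over all.

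Further neural members were miR-9-5p (-2.24 ± 0.58, adjusted p = 0.0685), miR-9-3p (-2.10 ± 0.60, adjusted p = 0.0929) and miR-138-5p (-0.38 ± 0.24). In the Dlk1-Dio3 list, 42 of 48 members were below control (median -0.44, adjusted p = 3.14e-07, adjusted p = 0.539 with an estimated correlation). 1 of them was lower adjusted over the list alone and 0 over all, with miR-409-5p (-1.37 ± 0.35), miR-369-5p (-0.89 ± 0.31), miR-381-3p (-0.96 ± 0.36) and miR-300-3p (-0.59 ± 0.23) in front. The remaining miRNAs with the smallest p, none passing in the main edgeR fit, were miR-342-3p (-0.68 ± 0.16, adjusted p = 0.0565), miR-193b-3p (0.95 ± 0.26, adjusted p = 0.0929), miR-6240 (1.5 ± 0.43), miR-328-3p (0.91 ± 0.26), miR-99a-5p (-0.46 ± 0.14) and miR-7667-5p, which was listed at 0 in all control libraries. With edgeR the myomiRs did not pass. miR-133a-3p/133b-3p differed by 0.63 ± 0.28, miR-206-3p by -0.42 ± 0.37, miR-1a-3p by -0.19 ± 0.25, miR-499-5p by -0.19 ± 0.52, miR-486a-5p/486b-5p by -0.04 ± 0.20 and miR-208b-3p by 0.06 ± 0.59. The count was 6 without HIIT 5 and 1 to 4 without any 1 of control 4 or 5, any lactate library, HIIT 3, inhibitor 2, 3, 4 or 6, or HIIT + inhibitor 1, 3, 4, 5 or 6.

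The inhibitor against control, in untrained mice, gave 32 miRNAs, 23 that rose and 9 that fell. Members of the imprinted Dlk1-Dio3 cluster rose, with miR-127-3p going from 976 ± 96.8 CPM (n = 5) to 2102 ± 461 CPM (n = 6), a log2 change of 1.11 ± 0.25 (adjusted p = 0.00572) and 6 of 6 mice above the control mean. miR-501-3p, encoded on the X chromosome, rose from 262 ± 96.3 to 679 ± 172 CPM (1.38 ± 0.25, adjusted p = 0.00336, 6 of 6). The miR-29 family, which represses collagens and DNA methyltransferases, fell, with miR-29a-3p going from 3252 ± 700.3 to 1646 ± 448 CPM (-0.98 ± 0.22, adjusted p = 0.00547, 6 of 6) and miR-29b-3p from 217 ± 23.1 to 106 ± 38.7 CPM (-1.03 ± 0.28, adjusted p = 0.0195, 6 of 6). These libraries were also the shallowest, as given above.

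In the Dlk1-Dio3 list 40 of 48 members were above control (median 0.76, camera adjusted p = 1.89e-06, adjusted p = 0.414 with an estimated correlation). 8 rose over all miRNAs and 11 adjusted over the list alone. Besides miR-127-3p they included miR-337-5p (1.63 ± 0.31), miR-411-5p (0.98 ± 0.23) and miR-382-5p (1.16 ± 0.28). All 3 members of the miR-29 list were below control (median -0.98, adjusted p = 0.00278, adjusted p = 0.347 with an estimated correlation). 2 fell over all and 3 adjusted over the list alone, and miR-29c-3p (-0.92 ± 0.34) did not pass over all in the main edgeR fit. All 12 DNA methylation and Polycomb regulators were below control (median -0.35, adjusted p = 0.000538, adjusted p = 0.347 with an estimated correlation). Of these miR-29a-3p, miR-29b-3p and miR-26b-5p (-0.61 ± 0.16) fell over all, 6 fell adjusted over the list alone, and miR-22-3p (-0.44 ± 0.14) did not pass in the main edgeR fit. The miR-29 family belongs to both lists. The 5 tested miR-30 members were below control (median -0.33, adjusted p = 0.0439, adjusted p = 0.414 with an estimated correlation), 0 past the threshold over all and 3 adjusted over the list alone. These 3 were miR-30c-5p (-0.93 ± 0.29), miR-30b-5p (-0.93 ± 0.33) and miR-30a-5p (-0.33 ± 0.12), and miR-30e-5p (-0.32 ± 0.16) did not pass.

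Other miRNAs that rose with the inhibitor were miR-320-3p (0.80 ± 0.17), miR-543-5p (2.10 ± 0.46), miR-127-5p (1.64 ± 0.39), miR-664-5p (0.82 ± 0.20) and miR-6240 (1.78 ± 0.43), with 6 of 6 mice above the control mean for each. Of these, miR-543-5p and miR-127-5p are the opposite arms of the Dlk1-Dio3 members miR-543-3p and miR-127-3p, so they are not separate from the cluster. miR-215-5p, an intestinal and renal miRNA, also passed (7.18 ± 1.49, adjusted p = 0.00547, 5 of 6), but its mean of 32.5 ± 67.2 CPM rested on inhibitor 1, at 169 CPM. Inhibitor 1 also stood apart in the scores of the epithelial list (1.75, other inhibitor mice -1.15 to 0.32) and the liver list (1.52, others -1.54 to -0.41). Of the epithelial list miR-200c-3p passed (2.10 ± 0.65, adjusted p = 0.0458), named after its values were seen. Other miRNAs that fell were miR-374b-5p (-0.82 ± 0.18), miR-204-5p (-0.83 ± 0.18), miR-25-3p (-0.55 ± 0.12), miR-22-5p (-0.69 ± 0.18), miR-186-5p (-0.55 ± 0.16) and miR-674-3p (-0.91 ± 0.27), each in 6 of 6 mice. Their adjusted p ran from 0.00547 for miR-374b-5p and miR-204-5p to 0.0342 for miR-674-3p. No myomiR passed with edgeR and TMM scaling. miR-1a-3p differed by -0.66 ± 0.25 (adjusted p = 0.0855, limma voom adjusted p = 0.00462), miR-499-5p by -1.30 ± 0.53 (limma voom adjusted p = 0.0480), miR-486a-5p/486b-5p by 0.40 ± 0.20 (total counts adjusted p = 0.0236), miR-206-3p by -0.36 ± 0.37, miR-133a-3p/133b-3p by -0.23 ± 0.27 and miR-208b-3p by -0.23 ± 0.60. With total counts the 32 became 71, 67 higher and 4 lower around a median of all miRNAs of 0.19, and miR-25-3p, miR-26b-5p, miR-22-5p, miR-186-5p and miR-674-3p no longer passed (adjusted p 0.0733 to 0.231). DESeq2 called 76, limma voom 113 and the GC-corrected fit 50, and the count was 19 to 21 without control 1, 3 or 5 or inhibitor 4, 52 without control 2 and 67 without inhibitor 1. The call of miR-29b-3p ended without control 3 or 5 or inhibitor 4 or 6 (adjusted p 0.0560 to 0.0783), and that of miR-26b-5p without control 5 (adjusted p = 0.0575). That of miR-22-5p ended without control 3, 4 or 5 or inhibitor 4 (adjusted p 0.0599 to 0.0804), that of miR-674-3p without control 1, 3 or 4 or inhibitor 2, 4, 5 or 6 (adjusted p 0.0507 to 0.136), and that of miR-186-5p without control 1, 3, 4 or 5, lactate 4 or inhibitor 4, 5 or 6 (adjusted p 0.0541 to 0.0806), after GC correction (adjusted p = 0.191), thinning to 1 depth (0.0589), with no filter (0.0954) and with only the groups compared (0.0554). The miR-30 list call ended with total counts (adjusted p = 0.162), thinning (0.0633), GC correction (0.0749), without the miRNAs with an improbable zero (0.0507) and without any 1 of 16 libraries (adjusted p 0.0504 to 0.0930), namely control 3 to 5, lactate 2 to 4, HIIT 1, 4 or 5, inhibitor 3, 4 or 6 or HIIT + inhibitor 1, 3, 4 or 5.

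**Figure D1:**
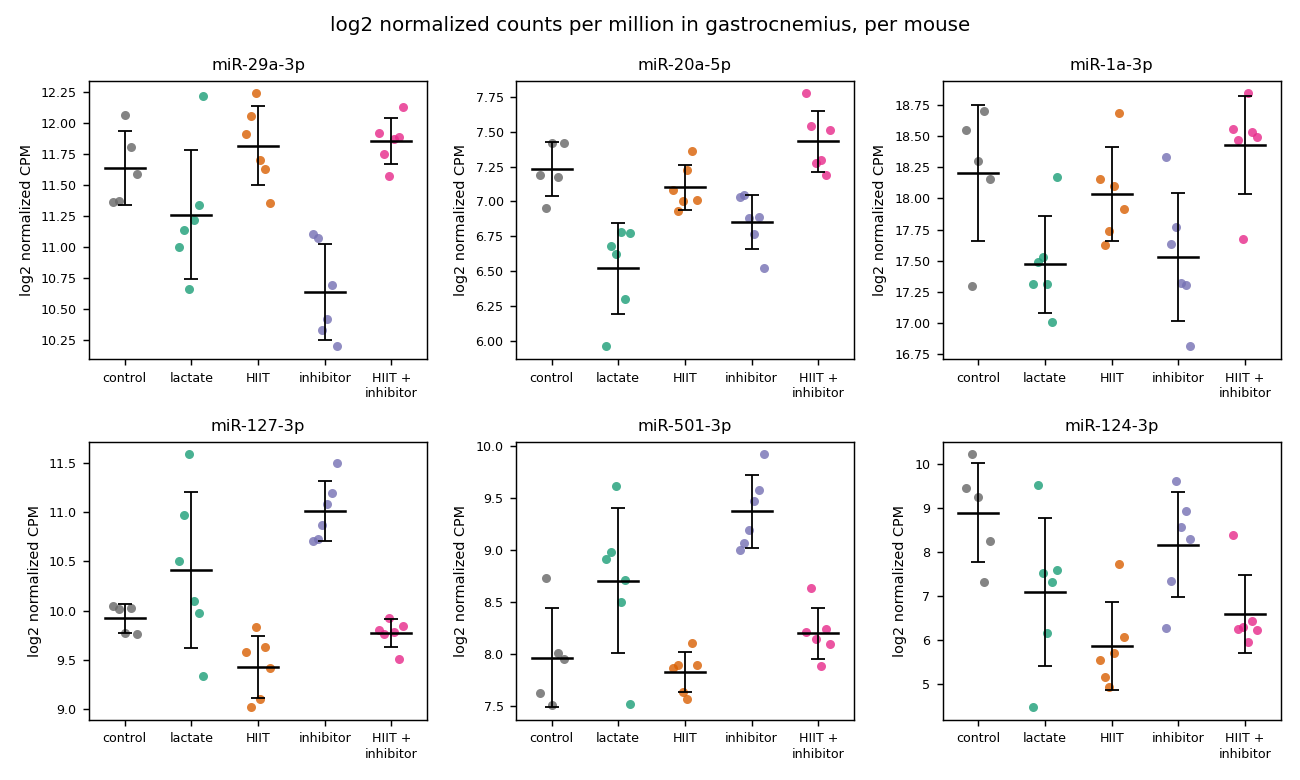
Normalized log2 counts per M (vertical axes) of 6 miRNAs by group, with 1 point per mouse (n = 5 in control, n = 6 in the other groups), the mean as a line and error bars of 1 SD on the log2 scale. All 6 inhibitor mice lie below all 6 HIIT + inhibitor mice for miR-29a-3p and above them for miR-127-3p and miR-501-3p.

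HIIT + inhibitor against inhibitor asked what training did in mice that received the inhibitor. Of 32 miRNAs that passed, 14 rose and 18 fell. The miR-29 family rose, miR-29a-3p from 1646 ± 448 to 3738 ± 476 CPM (1.18 ± 0.21, adjusted p = 0.00177) and miR-29b-3p from 106 ± 38.7 to 256 ± 47.0 CPM (1.27 ± 0.27, adjusted p = 0.00527), in 6 of 6 mice each. Muscle-enriched miR-1a-3p (0.86 ± 0.24, adjusted p = 0.0295) and miR-499-5p (1.70 ± 0.51, adjusted p = 0.0390), which lies within the slow myosin gene Myh7b, rose in 6 of 6 mice. Members of the Dlk1-Dio3 cluster fell, among them miR-127-3p from 2102 ± 461 to 877 ± 81.3 CPM (-1.26 ± 0.24, adjusted p = 0.00231, 6 of 6). Both this comparison and the preceding one contain the shallow inhibitor libraries, so their values are not independent.

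All 3 miR-29 members rose over all miRNAs (median 1.18, camera adjusted p = 7.40e-05, adjusted p = 0.130 with an estimated correlation) and 3 adjusted over the list alone, the last being miR-29c-3p (1.13 ± 0.33, adjusted p = 0.0329). In the Dlk1-Dio3 list 42 of 48 members were lower (median -0.68, adjusted p = 1.55e-07, adjusted p = 0.186 with an estimated correlation). 9 fell over all and 13 adjusted over the list alone, including miR-485-5p (-1.57 ± 0.32), miR-337-5p (-1.35 ± 0.29) and miR-409-5p (-1.53 ± 0.34). In the myomiR list 5 of 6 members were higher (median 0.89, adjusted p = 0.0310, adjusted p = 0.130 with an estimated correlation). 2 rose over all, and 4 rose and 1 fell adjusted over the list alone. The members that did not pass over all were miR-206-3p (0.92 ± 0.36), miR-208b-3p (1.4 ± 0.58), miR-133a-3p/133b-3p (0.41 ± 0.26) and miR-486a-5p/486b-5p (-0.54 ± 0.19). Of these, limma voom called miR-206-3p (adjusted p = 0.0347) and miR-208b-3p (0.0308), DESeq2 called miR-206-3p (0.0489), and total counts called miR-486a-5p/486b-5p (0.00425). Of the DNA methylation and Polycomb regulators 10 of 12 were higher (median 0.29, adjusted p = 0.00286, adjusted p = 0.186 with an estimated correlation). 3 rose over all, all of them miR-29 members, 5 rose adjusted over the list alone, and miR-22-3p (0.44 ± 0.14) did not pass. The 5 miR-30 members were higher (median 0.57, adjusted p = 0.00619, adjusted p = 0.186 with an estimated correlation), 2 over all and 4 adjusted over the list alone. miR-30e-5p (0.57 ± 0.15) and miR-30b-5p (1.09 ± 0.32) rose, and miR-30c-5p (0.85 ± 0.28) and miR-30a-5p (0.29 ± 0.12) did not pass. All 10 members of the miR-17-92 list were higher (median 0.44, adjusted p = 0.00286, adjusted p = 0.186 with an estimated correlation), 2 over all and 4 adjusted over the list alone. miR-20a-5p (0.58 ± 0.14) and miR-106b-5p (0.73 ± 0.20) rose, and miR-19b-3p (1.58 ± 0.50) and miR-25-3p (0.35 ± 0.12) did not pass.

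Also rising in 6 of 6 mice were miR-185-5p (0.53 ± 0.14), miR-374b-5p (0.65 ± 0.17) and miR-186-5p (0.57 ± 0.15). Also falling in 6 of 6 mice were miR-501-3p (-1.19 ± 0.24, adjusted p = 0.00347), miR-543-5p (-1.93 ± 0.43), miR-664-5p (-0.78 ± 0.18), miR-433-3p (-1.46 ± 0.35), miR-411-5p (-0.87 ± 0.21) and miR-455-3p (-0.97 ± 0.26). Of these, miR-433-3p and miR-411-5p belong to the Dlk1-Dio3 list, and miR-543-5p is the opposite arm of its member miR-543-3p. With total counts 90 passed, 7 higher and 83 lower around a median of all miRNAs of -0.27, and miR-20a-5p, miR-30b-5p, miR-30e-5p, miR-106b-5p, miR-185-5p, miR-186-5p and miR-374b-5p no longer passed. DESeq2 called 68 and limma voom 85, and the count was 13 without HIIT + inhibitor 6, 20 without HIIT + inhibitor 1 or inhibitor 5, and 67 without inhibitor 1. The call of miR-1a-3p ended without any 1 of inhibitor 4, 5 or 6 or HIIT + inhibitor 1, 4, 5 or 6, with an adjusted p of 0.0502 to 0.0671. That of miR-499-5p ended without any 1 of inhibitor 2 to 5 or HIIT + inhibitor 3 to 6 (adjusted p 0.0502 to 0.0893) and with a robust fit (adjusted p = 0.0533). Those of miR-29c-3p and miR-30b-5p ended without any 1 of inhibitor 3 to 6 or HIIT + inhibitor 1, 4, 5 or 6 (adjusted p 0.0502 to 0.0978). Further calls ended without HIIT + inhibitor 6 for miR-30e-5p (adjusted p = 0.0848), without that library or inhibitor 6 for miR-374b-5p (0.0543 and 0.0736), without HIIT + inhibitor 1 or 6 for miR-455-3p (0.0567 and 0.0586), without HIIT + inhibitor 6 or inhibitor 5 or 6 for miR-186-5p (0.0582 to 0.0586) and without HIIT + inhibitor 1 or 6 or inhibitor 4, 5 or 6 for miR-106b-5p (0.0532 to 0.0827). That of miR-186-5p also ended with only the groups compared (adjusted p = 0.0506), thinning (0.0528) and GC correction (0.36, adjusted p = 0.128). The myomiR list call ended without inhibitor 1 or 5 or HIIT + inhibitor 5 (adjusted p 0.0530 to 0.0627) and after GC correction (adjusted p = 0.0566), and that of miR-30 with total counts (adjusted p = 0.0554).

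**Figure D2:**
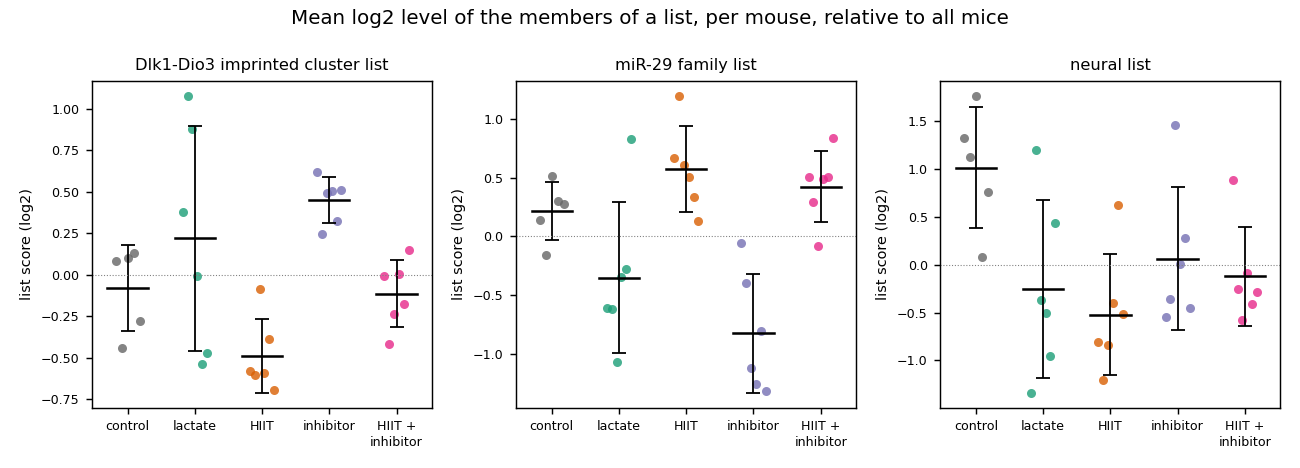
Scores of miRNA lists (vertical axes, mean log2 CPM of the members after centering each on its mean over the 29 libraries) by group, with 1 point per mouse, the mean as a line and error bars of 1 SD. For the Dlk1-Dio3 cluster the inhibitor group stands at 0.45 ± 0.14 (n = 6) against -0.08 ± 0.26 in control (n = 5), and lactate spreads most, at 0.22 ± 0.68 (n = 6).

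HIIT + inhibitor against control gave no miRNA with edgeR, 24 had an unadjusted p under 0.05, DESeq2 called 1 and limma voom 0. The DESeq2 call was miR-3473a (-23.66, adjusted p = 0.000353), which rests on doubtful zeros, as this miRNA was at 0 in 23 of the 29 libraries, improbably so in each, and held 44 to 167 counts in the other 6. Nerve-enriched miRNAs were lower as a list, with all 6 members below control (median -1.15, camera adjusted p = 2.19e-05, adjusted p = 0.138 with an estimated correlation), 3 of them adjusted over the list alone and 0 over all. miR-124-3p was at 119 ± 106 CPM (n = 6) against 594 ± 401 CPM (n = 5, log2 difference -2.32 ± 0.68, adjusted p = 0.511), miR-9-5p at -1.86 ± 0.57, miR-9-3p at -1.81 ± 0.60 and miR-138-5p at -0.37 ± 0.24. The other miRNAs with the smallest p, none passing in the main edgeR fit, were miR-99a-5p (-0.41 ± 0.14), miR-6240 (1.18 ± 0.43), miR-146a-5p (-0.62 ± 0.24), miR-671-5p (0.47 ± 0.19), miR-215-5p (3.57 ± 1.43), miR-7667-5p, listed at 0 in all control libraries, and miR-3473a, listed at 0 in all HIIT + inhibitor libraries. The myomiRs differed by 1.17 ± 0.60 for miR-208b-3p, 0.56 ± 0.37 for miR-206-3p, 0.40 ± 0.52 for miR-499-5p, 0.19 ± 0.25 for miR-1a-3p, -0.14 ± 0.20 for miR-486a-5p/486b-5p and 0.17 ± 0.27 for miR-133a-3p/133b-3p, each with an adjusted p of 0.990.

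HIIT + inhibitor against HIIT asked what the inhibitor did in trained mice. No miRNA passed with edgeR, with 35 at an unadjusted p under 0.05, 2 with DESeq2 and 0 with limma voom. The 2 were miR-493-5p (2.24, adjusted p = 0.0329) and miR-3473a (-22.16, adjusted p = 0.000575), the latter again on doubtful zeros. The level of miR-493-5p was low, at 3.92 ± 1.79 CPM with HIIT + inhibitor and 0.81 ± 0.43 CPM with HIIT. The Dlk1-Dio3 cluster was higher as a list, with 37 of 48 members above HIIT (median 0.40, camera adjusted p = 1.71e-08, adjusted p = 0.328 with an estimated correlation), 2 adjusted over the list alone and 0 over all. The smallest p, none passing in the main edgeR fit, belonged to miR-493-5p (2.22 ± 0.58, adjusted p = 0.250), miR-381-3p (1.24 ± 0.34), miR-3102-3p (-0.86 ± 0.25), miR-409-5p (1.15 ± 0.34), miR-193b-3p (-0.70 ± 0.24), miR-29b-1-5p (-0.41 ± 0.14), miR-379-5p (0.66 ± 0.23), the satellite-cell and regenerating-muscle miR-206-3p (0.98 ± 0.36), miR-130a-3p (0.56 ± 0.21) and the myeloid miR-223-3p (-0.61 ± 0.23). The cluster also held miR-369-5p (0.77 ± 0.30). Other myomiRs were miR-208b-3p (1.11 ± 0.57), miR-133a-3p/133b-3p (-0.46 ± 0.26), miR-1a-3p (0.38 ± 0.24), miR-499-5p (0.59 ± 0.50) and miR-486a-5p/486b-5p (-0.10 ± 0.19). Without HIIT + inhibitor 5 the count was 3, and with only the groups compared it was 1.

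Whether the inhibitor changed the response to training was tested with the interaction, the HIIT + inhibitor minus inhibitor difference less the HIIT minus control difference. No miRNA passed with edgeR (lowest adjusted p = 0.0921, 88 at an unadjusted p under 0.05), DESeq2 called 29 and limma voom 47. For several lists the difference between trained and untrained mice was shifted upward with the inhibitor. These lists were the myomiRs, miR-29, miR-30, miR-17-92 with paralogous clusters, the DNA methylation and Polycomb regulators and the neural miRNAs. This contrast contains the shallow inhibitor libraries, for which depth and group coincide. With the inhibitor alone, medians against control were -0.98 for miR-29, -0.33 for miR-30, -0.31 for miR-17-92, -0.35 for the regulators and -0.30 for myomiRs. In the same order they were 0.33, 0.10, -0.01, -0.08 and -0.12 with HIIT. With HIIT + inhibitor they were 0.21, 0.03, 0.14, -0.06 and 0.30. The neural miRNAs had a median of -1.91 without the inhibitor, while with it 3 members were higher and 3 lower in trained mice (median -0.25, camera adjusted p = 0.744). All 6 were also below control with the inhibitor alone (median -0.98) and with HIIT + inhibitor (median -1.15). Their interaction therefore does not separate a changed response to training from the lower level in the inhibitor group. The largest medians were 1.47 for the 6 neural miRNAs (camera adjusted p = 0.0345, adjusted p = 0.318 with an estimated correlation) and 1.19 for the 6 myomiRs (adjusted p = 0.0461, adjusted p = 0.302 with an estimated correlation). Medians were 0.80 for miR-29 (adjusted p = 0.0345, adjusted p = 0.318 with an estimated correlation), 0.53 for miR-17-92 (adjusted p = 0.0182, adjusted p = 0.318 with an estimated correlation), 0.46 for miR-30 (adjusted p = 0.0487, adjusted p = 0.318 with an estimated correlation) and 0.46 for the DNA methylation and Polycomb regulators (adjusted p = 0.00207, adjusted p = 0.302 with an estimated correlation).

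No member of these 6 lists passed over all miRNAs in the interaction. Adjusted over the list alone, 3 myomiRs, 4 members of the miR-17-92 list and 2 DNA methylation and Polycomb regulators passed. So did 1 miR-29 member, but 0 miR-30 members and 0 neural miRNAs. miR-1a-3p passed with DESeq2 (adjusted p = 0.0471) and limma voom (0.0129), and miR-486a-5p/486b-5p with total counts (0.0405). Values were 1.05 ± 0.35 for miR-1a-3p, 1.34 ± 0.51 for miR-206-3p, 1.90 ± 0.72 for miR-499-5p, -0.50 ± 0.28 for miR-486a-5p/486b-5p, 1.33 ± 0.82 for miR-208b-3p, -0.23 ± 0.38 for miR-133a-3p/133b-3p, 1.0 ± 0.30 for miR-29a-3p, 0.80 ± 0.47 for miR-29c-3p, and 0.61 ± 0.38 for miR-29b-3p. In the list of miR-17-92 and paralogous clusters, values were 0.71 ± 0.21 for miR-20a-5p, 0.53 ± 0.17 for miR-25-3p, 0.85 ± 0.29 for miR-106b-5p and 0.53 ± 0.21 for miR-17-5p. In the other lists they were 0.82 ± 0.23 for miR-26b-5p, 0.41 ± 0.20 for miR-22-3p, 0.44 ± 0.23 for miR-342-3p, 1.65 ± 0.79 for miR-9-5p and 1.56 ± 0.82 for miR-9-3p. They were 0.50 ± 0.33 for miR-138-5p, 1.37 ± 0.91 for miR-124-3p, 0.96 ± 0.46 for miR-30b-5p, 0.46 ± 0.22 for miR-30e-5p, 0.34 ± 0.17 for miR-30a-5p and 0.82 ± 0.41 for miR-30c-5p. The other miRNAs with the smallest p were miR-664-5p (-1.12 ± 0.27), miR-320-3p (-0.93 ± 0.23), miR-324-5p (-0.81 ± 0.22), miR-6240 (-2.10 ± 0.58), miR-1247-5p (-2.42 ± 0.68), miR-215-5p (-6.23 ± 1.79) and miR-615-3p (-1.13 ± 0.33). With total counts 47 passed, 1 higher and 46 lower around a median of all miRNAs of -0.39, and with a mean of at least 50 CPM 9 passed. The count was 16 without inhibitor 1, 8 without control 2, 4 without HIIT 4 and 2 without lactate 6, and these list calls were fragile. Those of miR-30, miR-29, miR-17-92 and myomiRs ended with total counts (adjusted p = 0.262, 0.0527, 0.0567 and 0.0567), and those of myomiRs, miR-30 and miR-29 after GC correction (adjusted p = 0.0922, 0.113 and 0.139). That of miR-30 also ended with thinning (adjusted p = 0.0693) and without the miRNAs with an improbable zero (0.0576). The calls of miR-17-92, neural, miR-29, myomiRs and miR-30 ended without any 1 of 1, 6, 7, 11 and 18 libraries, HIIT 3 being among them each time (adjusted p 0.0504 to 0.0921 over these).

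Lactate against HIIT asked directly how lactate injection and training differed. 22 miRNAs passed, 18 higher and 4 lower with lactate. Dlk1-Dio3 members were higher, with miR-409-5p at 77.0 ± 57.9 CPM with lactate against 19.6 ± 1.80 CPM with HIIT (n = 6 each, 1.97 ± 0.35, adjusted p = 0.00176, 6 of 6) and miR-127-3p at 1545 ± 877 against 704 ± 149.9 CPM (1.13 ± 0.24, adjusted p = 0.00665, 5 of 6). Lower with lactate were miR-29b-3p (-1.10 ± 0.27, adjusted p = 0.0143), miR-20a-5p (-0.56 ± 0.14, adjusted p = 0.0166), miR-6240 (-1.53 ± 0.40) and the myeloid miR-223-3p (-0.78 ± 0.23), in 6 of 6 mice each.

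In the Dlk1-Dio3 list 43 of 48 members were higher with lactate (median 0.87, camera adjusted p = 1.64e-14, adjusted p = 0.183 with an estimated correlation). 11 rose over all and 20 adjusted over the list alone, including miR-369-5p (1.36 ± 0.30, 5 of 6) and miR-382-5p (1.14 ± 0.27, 4 of 6). The mice were split, with lactate 1 to 3 at the scores of 0.38, 1.08 and 0.88 given above, lactate 4 at -0.01, and lactate 5 and 6 at -0.54 and -0.47, near the HIIT mean of -0.49. The exact permutation test of the score did not pass for this list (difference 0.71, adjusted p = 0.0835) or for any other list in this comparison. The 3 miR-29 members were lower (median -0.90, adjusted p = 0.00273, adjusted p = 0.201 with an estimated correlation). 1 fell over all and 3 adjusted over the list alone, with miR-29c-3p at -0.90 ± 0.33 and miR-29a-3p at -0.50 ± 0.21. Of the miR-17-92 list 9 of 10 were lower (median -0.34, adjusted p = 0.00553, adjusted p = 0.309 with an estimated correlation). 1 fell over all and 3 adjusted over the list alone, with miR-106b-5p (-0.63 ± 0.20), miR-93-5p (-0.41 ± 0.13) and miR-18a-5p (-0.88 ± 0.37) not passing over all. All 5 miR-30 members were lower (median -0.40, adjusted p = 0.0282, adjusted p = 0.309 with an estimated correlation) and 8 of 9 let-7 members (median -0.27, adjusted p = 0.0282, adjusted p = 0.538 with an estimated correlation), with 0 adjusted over the list alone and 0 over all in both. Their lowest p were those of miR-30e-5p (-0.40 ± 0.15), miR-30b-5p (-0.72 ± 0.32), miR-30a-5p (-0.26 ± 0.12), miR-30c-5p (-0.59 ± 0.28), let-7g-5p (-0.41 ± 0.15), let-7i-5p (-0.31 ± 0.11), let-7a-5p (-0.36 ± 0.16) and miR-98-5p (-0.31 ± 0.18). The DNA methylation and Polycomb regulators were lower (9 of 12, median -0.29, adjusted p = 0.0282, adjusted p = 0.352 with an estimated correlation), although miR-342-3p, reported to target DNMT1, rose (0.64 ± 0.16) while miR-29b-3p fell. Adjusted over the list alone 1 rose and 3 fell, and miR-101a-3p/101b-3p/101c was at -0.72 ± 0.27.

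Also higher with lactate than with HIIT were miR-493-5p (3.0 ± 0.58, 6 of 6), miR-543-5p (2.00 ± 0.43, 5 of 6), miR-501-3p (1.0 ± 0.24, 5 of 6), miR-127-5p (1.51 ± 0.36, 5 of 6) and miR-299a-5p/299b-5p (1.45 ± 0.37, 4 of 6). Of these, miR-299a-5p/299b-5p belongs to the Dlk1-Dio3 list, and miR-543-5p and miR-127-5p are the opposite arms of its members miR-543-3p and miR-127-3p. miR-493-5p is not among the tested members of the list, which does not place it outside the cluster. Its level was low, at 6.78 ± 7.21 CPM with lactate and 0.81 ± 0.43 CPM with HIIT. No myomiR passed with edgeR. miR-1a-3p was at -0.56 ± 0.24 (limma voom adjusted p = 0.0429), miR-499-5p at -0.93 ± 0.50, miR-133a-3p/133b-3p at -0.43 ± 0.26, miR-208b-3p at -0.76 ± 0.57, miR-486a-5p/486b-5p at 0.22 ± 0.19 and miR-206-3p at 0.19 ± 0.35. With only the groups compared in the fit, which has fewer libraries, 0 passed, and the cause was not tested. Total counts gave 36, 34 higher and 2 lower around a median of all miRNAs of 0.14. DESeq2 called 40 and limma voom 38, and the count was 48 without lactate 6 and 13 without lactate 3. The calls of miR-127-5p (adjusted p = 0.0509) and miR-299a-5p/299b-5p (adjusted p = 0.0531) ended without lactate 3, that of miR-29b-3p without lactate 2 or 3 (adjusted p 0.0691 to 0.0812) and that of miR-20a-5p without lactate 3 or HIIT 1 or 4 (adjusted p 0.0688 to 0.0759). That of miR-6240 ended without lactate 2, 3 or 4 or HIIT 1 or 4 (adjusted p 0.0522 to 0.0882). That of miR-223-3p ended without any 1 of 20 libraries (adjusted p 0.0503 to 0.216). It held without control 1 or 2, lactate 6, HIIT 6, inhibitor 1, 5 or 6 or HIIT + inhibitor 2 or 6. The list calls of the DNA methylation and Polycomb regulators, let-7 and miR-30 ended with total counts (adjusted p = 0.0999, 0.304 and 0.0999), without the miRNAs with an improbable zero (0.0508 for each) and without any 1 of 12, 9 and 13 libraries, lactate 1 and 2 being among them each time (adjusted p from 0.0505).

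With camera the lists that passed in none of the 8 comparisons were the exercise-associated miRNAs (lowest adjusted p = 0.152), smooth muscle (0.234), leukocyte (0.234), epithelial (0.207), connective tissue (0.406), liver (0.0538) and inflammation miRNAs (0.0633), and the miR-181 (0.157), miR-15/16 (0.0610) and miR-23/27/24 lists (0.222). In the exact permutation test of list scores miR-181 passed in inhibitor against control (adjusted p = 0.0195) and the exercise-associated list in HIIT + inhibitor against inhibitor (0.14, adjusted p = 0.0260), which ended after GC correction (0.01, adjusted p = 0.864). In 14 pairs of a list and a comparison, none passing (lowest adjusted p = 0.207), the median, mean and test of a list differed in sign. Examples are the exercise-associated list in HIIT against control (median -0.05, mean 0.01, tested lower), the epithelial list in inhibitor against control (median 0.72, mean 0.47, tested lower) and in HIIT + inhibitor against inhibitor (median -0.52, mean -0.09, tested higher), and miR-15/16 in lactate against HIIT (median -0.08, mean -0.05, tested higher). Lists with fewer than 3 tested members were read by miRNA, and none of these passed. In HIIT + inhibitor against inhibitor the endothelial miR-126a-5p differed by 0.64 ± 0.23 (adjusted p = 0.0699). In the same comparison the red-cell miRNAs miR-451a by 1.75 ± 0.68 (adjusted p = 0.101) and miR-144-3p by 1.35 ± 0.88 (adjusted p = 0.320), the hypoxia-induced miR-210-3p by 0.35 ± 0.21 (adjusted p = 0.292) and miR-34c-5p by 0.81 ± 0.48 (adjusted p = 0.274), each the lowest adjusted p of that miRNA. The lowest were found in inhibitor against control for miR-34a-5p (-0.40 ± 0.24, adjusted p = 0.290) and in lactate against control for miR-126a-3p (-0.36 ± 0.17, adjusted p = 0.271).

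How far the lactate and training profiles resembled each other was read from log2 fold changes across the 481 miRNAs, which are not independent replicates. Lactate against control and HIIT against control correlated with a Pearson r of 0.471 and a Spearman rho of 0.375. Since both use the same control libraries, unchanged groups simulated against them gave r = 0.548 ± 0.044 (SD, 100 simulations), above the observed value. The covariance was 0.165 against 0.126 ± 0.016 simulated, and with the controls divided between the comparisons the median r over 10 divisions was 0.139, against -0.0134 ± 0.0482 simulated. HIIT and HIIT + inhibitor, each against control, gave r = 0.585 and rho = 0.453 (simulated r 0.544 ± 0.041), a covariance of 0.170 (simulated 0.127 ± 0.015) and r = 0.176 with divided controls (simulated 0.00144 ± 0.0408). The simulated SDs leave out the correlation between miRNAs, so a value beyond them is not a test of resemblance.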

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

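The tests of technical explanations below, the counts over other splits, the thinning, the GC correction and the list-score tests were chosen only after the results were seen.

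Of 149 groups of 5 or 6 values, 8 held a library far from the others by Dixon's 95% criterion, against 7.45 that chance gives at 5 in 100. In 2 cases the share of the 10 most abundant miRNAs stood apart: 72.9% in lactate 6 (95% Wilson interval 72.88 to 72.95, others of its group 65.1 to 68.0) and 66.1% in HIIT + inhibitor 3 (66.04 to 66.12, others 71.7 to 74.0). HIIT + inhibitor 3 also had miR-1a-3p at 209368 CPM (others 361491 to 469035). Among the inhibitor libraries miR-411-5p was at 185 CPM in inhibitor 6 (others 91.4 to 110.3), miR-499-5p at 6.24 CPM in inhibitor 5 (25.0 to 52.7) and miR-433-3p at 8.42 CPM in inhibitor 1 (18.4 to 27.5). In HIIT, miR-493-5p was listed at 0 in HIIT 5 (0.766 to 1.21 CPM) and miR-29b-3p was at 598 CPM in HIIT 2 (257 to 323). Without lactate 6, 23 miRNAs differed between lactate and control instead of 1. Without inhibitor 1, 67 instead of 32 differed between the inhibitor group and control.

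The difference between trained and untrained mice was shifted upward with the inhibitor, by the interaction test, for 6 lists: myomiRs (median 1.19), the DNA methylation and Polycomb regulators (0.46), neural miRNAs (1.47), miR-30 (0.46), miR-29 (0.80) and miR-17-92 (0.53). The interaction contains the shallow inhibitor libraries, for which depth and group coincide. For the neural list the median was -1.91 without the inhibitor, and with it 3 members were higher and 3 lower (median -0.25, camera adjusted p = 0.744). All 6 neural miRNAs were also below control with the inhibitor alone (median -0.98), so a changed response to training is not separated from this lower level. Of 100 splits 3 gave as many lists, the highest other being 6, with no adjustment over 17 such counts. As 0 lists passed with an estimated correlation and 5 of the 6 calls ended with 1 library left out, chance is not excluded. No single miRNA passed, and a count of 0 cannot be tested against other splits (100 of 100 reach it, highest other 3).

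The first pattern weighed is the difference between the inhibitor group and control. The tables argue against lower depth as its whole cause, since 27 of 32 calls were kept after thinning every library to the smallest total, and against a GC trend between libraries, since 30 of 32 were kept after correction. They also argue against 1 unusual library, since the fewest kept with a control or inhibitor library left out was 19, without control 3. The 32 miRNAs argue against chance (1 of 100 splits, highest other 10). This share is the smallest that 100 splits can give and is not adjusted over the other such counts, so chance is not excluded. Nor could chance be excluded for the 4 lists (15 of 100, highest other 6). The lower yield of these libraries and an effect of the inhibitor, which the design names, both stay open, because depth and group coincide and only 1 batch label was given.

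The second pattern is the higher Dlk1-Dio3 cluster in the inhibitor group. A GC trend is argued against by the cluster score, which differed by 0.53 before and 0.69 after correction (exact permutation test, adjusted p = 0.0260 after). Scaling factors as the source of the rise are argued against by total counts, where the cluster median was 1.002 (0.76 with TMM factors, median of all miRNAs 0.19). The connective tissue score was -0.26 relative to control (-0.43 to -0.13 with a library left out). It stood at -0.15 ± 0.37 with the inhibitor and 0.11 ± 0.42 in control (exact permutation p = 0.301). It showed no rise, but this spread is too wide to exclude more connective tissue. Scores of the smooth muscle (-0.60), leukocyte (-0.19), neural (-0.95) and liver (-0.90) lists did not rise with the cluster either. The epithelial score (-0.13) cannot decide, as it was at -0.02 ± 0.99 with the inhibitor. The fold changes of its members had a median of 0.72, and 1 member rose over all miRNAs. An effect of the inhibitor, more connective or epithelial tissue and a change in a cell type without a list here stay open.

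The last pattern is the lower neural list in trained mice, which is not particular to training, since all 6 neural miRNAs were also below control with lactate (median -0.96) and with the inhibitor (median -0.98, camera adjusted p = 0.0988). Varying neural RNA between samples is a candidate explanation, as within groups miR-124-3p and miR-9-5p deviated together across 29 libraries (r = 0.690, permutation p = 0.00037, adjusted 0.0016; rho = 0.643, permutation p = 0.00085, adjusted 0.0017; 6 pairs tested; r = 0.622 without the 2 farthest libraries). Of the other pairs, miR-137-3p, which is outside the list, went with miR-124-3p (r = 0.627, adjusted permutation p = 0.0016) and miR-9-5p (0.596, 0.0027) and miR-9-5p with miR-138-5p (0.506, 0.017), while miR-138-5p did not pass with miR-124-3p (0.0874, 0.68) or miR-137-3p (0.334, 0.16; rho = 0.436, adjusted permutation p = 0.046). The pattern is not explained by 1 unusual control library, since in HIIT against control the median of all 6 members stayed at -1.39 or further from 0 with any control library left out (-1.91 with all, the nearest being without control 3, camera adjusted p = 5.84e-05). The neural score differed from control by -1.27 with lactate, -1.53 with HIIT, -0.95 with the inhibitor and -1.13 with HIIT + inhibitor, none passing the exact permutation test (adjusted p = 0.134, 0.117, 0.117 and 0.273), so a difference of the control samples, dissection and an effect of training all stay open.

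For the remaining comparisons, chance could not be excluded for lactate against control (real count 1, highest other 24, 8 of 100 splits as large), nor for its 5 lists (highest other 5, 5 of 100), the 2 lists in HIIT against control (highest other 4, 29 of 100), the list in HIIT + inhibitor against control (1, highest other 3, 48 of 100) or that in HIIT + inhibitor against HIIT (1, highest other 4, 62 of 100). The counts of 0 miRNAs in these last 3 comparisons cannot be tested this way, since all 100 splits reach 0 (highest other 1, 1 and 3). In lactate against HIIT chance could not be excluded for the 22 miRNAs (5 of 100, highest other 39). For its 6 lists 3 of 100 splits gave as many (highest other 6), and for the 6 lists in HIIT + inhibitor against inhibitor 4 of 100 (highest other 8). Since these shares are not adjusted over 17 such counts and no list passed with an estimated correlation, these counts do not exclude chance. By list score, the exact permutation test passed in HIIT + inhibitor against inhibitor for myomiRs and Dlk1-Dio3 (adjusted p = 0.0195 each). It also passed there for miR-29, miR-30 and the DNA methylation and Polycomb regulators (0.0260 each), but not for miR-17-92 (0.0835). In lactate against HIIT no list passed it. The split with 24 calls, against a real count of 1, may reflect a structure of the lactate and control samples, which was not tested further. The 32 miRNAs in HIIT + inhibitor against inhibitor (1 of 100, highest other 11) argue against chance. So do the 65 for any difference among the 5 groups (1 of 100, highest other 4). Both shares are the smallest that 100 splits can give and are likewise not adjusted, so chance is not excluded.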

How the results depend on the processing

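The fits with every library thinned to 1 depth, with GC correction and without the miRNAs with an improbable zero, and the lactate and inhibitor correlation, were chosen only after the results were seen.

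Of the values of single miRNAs under other settings, 2228 kept their direction and side of the threshold, 48 no longer passed, 10 reversed and the others came to pass. With 1 library left out 5844 were kept, 108 no longer passed, 19 reversed and 177 came to pass. Of the list calls 161 were kept and 56 lost under other settings, and 796 kept and 103 lost with 1 library left out. None of the list calls changed its camera direction. The cause of the changes below was not tested, except that fits of only the groups compared have fewer libraries.

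The count of miRNAs in lactate against control (1) was 5 with RLE scaling, 28 with total counts, 0 with no filter, 13 with a mean of at least 50 CPM, 28 with DESeq2, 50 with limma voom, 0 with only the groups compared, 0 with a replicate block, 0 thinned, 2 GC-corrected and 4 without miRNAs with an improbable zero. In HIIT against control (0) it was 2 with RLE scaling, 6 with no filter, 7 with at least 50 CPM, 11 with DESeq2, 8 with limma voom, 3 with only the groups compared, 2 GC-corrected and 1 without improbable zeros. In inhibitor against control (32) it was 71 with total counts, 76 with DESeq2, 113 with limma voom and 50 GC-corrected. HIIT + inhibitor against control (0) gave 1 with DESeq2, and against HIIT (0) 2 with DESeq2 and 1 with only the groups compared. HIIT + inhibitor against inhibitor (32) gave 90 with total counts, 68 with DESeq2 and 85 with limma voom. Lactate against HIIT (22) gave 36, 40 and 38 with these, and 0 with only the groups compared. The interaction (0) gave 47 with total counts, 9 with at least 50 CPM, 29 with DESeq2 and 47 with limma voom. Any difference (65) gave 106, 121 and 133 with total counts, DESeq2 and limma voom. Of the 31 list calls 0 were kept with an estimated correlation, 30 with RLE scaling, 20 with total counts, 29 thinned, 26 GC-corrected and 25 without miRNAs with an improbable zero. The 6 lost without improbable zeros were let-7 in lactate against control (adjusted p = 0.0622), miR-30 in inhibitor against control (0.0507) and in the interaction (0.0576), and let-7, miR-30 and the DNA methylation and Polycomb regulators in lactate against HIIT (0.0508 each).

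With 1 library left out the counts ran from 0 to 23 in lactate against control, 0 to 6 in HIIT against control, 19 to 67 in inhibitor against control, 0 to 3 in HIIT + inhibitor against HIIT, 13 to 67 in HIIT + inhibitor against inhibitor, 13 to 48 in lactate against HIIT and 0 to 16 in the interaction. HIIT + inhibitor against control stayed at 0, any difference ran from 46 to 79 and lists from 23 to 34. The correlation of lactate and HIIT fold changes (0.471) was 0.139 with controls split and ran from 0.403 to 0.562. That of HIIT and HIIT + inhibitor (0.585) was 0.176 and ran from 0.514 to 0.666. That of lactate and inhibitor (0.610) was 0.321 split and 0.797 with at least 50 CPM, and ran from 0.543 to 0.669.

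Reversals in the settings run occurred in values that did not pass. With total counts miR-206-3p was at 0.0328 in lactate against control, miR-486a-5p/486b-5p at 0.0286 in HIIT against control, and miR-133a-3p/133b-3p at 0.00803 and miR-208b-3p at 0.0549 in inhibitor against control. In HIIT against control miR-486a-5p/486b-5p was also at 0.0429 with at least 50 CPM, 0.0312 with limma voom and 0.0125 without improbable zeros, and miR-208b-3p at -0.35 with limma voom and -0.59 with a replicate block. In the interaction miR-133a-3p/133b-3p was at 0.21 with limma voom.

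With 1 library left out, miR-206-3p ran from -0.382 (without control 5) to 0.0184 (without control 2) in lactate against control and from -0.00151 (without HIIT 2) to 0.417 (without HIIT 6) in lactate against HIIT. In HIIT against control miR-499-5p ran from -0.528 (without HIIT 3) to 0.0998 (without control 4), miR-486a-5p/486b-5p from -0.124 (without control 3) to 0.0679 (without control 2) and miR-208b-3p from -0.692 (without HIIT 6) to 0.456 (without control 4). In inhibitor against control miR-208b-3p ran from -0.812 (without inhibitor 6) to 0.164 (without control 4). In HIIT + inhibitor against HIIT miR-486a-5p/486b-5p ran from -0.183 (without HIIT + inhibitor 5) to 0.0392 (without HIIT 1), and in the interaction miR-133a-3p/133b-3p from -0.397 (without HIIT + inhibitor 5) to 0.197 (without HIIT 2). Library measures were recomputed only with a control library left out. Relative to control, total counts ran from -0.430 to 0.0936 M with HIIT and from -0.409 to 0.114 M with HIIT + inhibitor (without control 2 and 3). The number of miRNAs with a count ran from -1.83 to 14.9 with lactate (without control 4 and 3). With HIIT the percent in the most abundant miRNA ran from -3.98 to 1.05 and that in the first 10 from -1.46 to 0.469 (without control 2 and 4). The 2 library differences that passed stayed at 2 with any control library left out, and no inhibitor library was left out for them.

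With a replicate block the counts were 0, 0, 34, 0, 0, 30, 18 and 0 in the 8 comparisons and 58 for any difference. Replicate numbers showed no pairing, as 56 pairs with the same number had a mean r of 0.00929 (other pairs -0.00185) and 5 of 29 libraries fitted best with their own number. Adding up repeated names did not apply, since no name was repeated. How far depth limits the detection of small changes was not separated from the number of mice and their spread. In the simulated data, at the depths of these libraries, edgeR recovered 25.4% of 1.5-fold, 46.3% of 2-fold and 72.7% of 4-fold changes in HIIT + inhibitor against control. Many miRNAs were changed at once there, so these shares can overstate the recovery in the real data.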

Other observations

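The exact permutation tests of list scores, the comparisons of disjoint pairs, and the GC trends were chosen only after the results were seen.

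List scores per library were compared by an exact permutation test in every comparison of 2 groups, adjusted over the lists. In inhibitor against control 4 lists passed: DNA methylation and Polycomb regulators (-0.51, adjusted exact p = 0.0390), miR-29 (-1.04, 0.0390), miR-181 (0.35, 0.0195) and Dlk1-Dio3 (0.53, 0.0195). In HIIT + inhibitor against inhibitor 6 passed: myomiRs (0.90, adjusted exact p = 0.0195), Dlk1-Dio3 (-0.57, 0.0195), and miR-29 (1.25), miR-30 (0.59), DNA methylation and Polycomb regulators (0.45) and the exercise-associated list (0.14), each at 0.0260. After GC correction the exercise-associated score differed by 0.01 (adjusted exact p = 0.864). No list passed in the other comparisons of 2 groups. The lowest adjusted exact p there was 0.0835, reached by 7 lists in lactate against HIIT, among them Dlk1-Dio3 (0.71, exact p = 0.0325) and miR-29 (-0.92, exact p = 0.0173).

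The fold changes of lactate and of the inhibitor against control correlated across 481 miRNAs, which are not independent replicates, with r = 0.610 and rho = 0.658. Simulated unchanged groups gave r = 0.546 ± 0.048 and a mean rho of 0.502. The covariance was 0.286 against 0.128 ± 0.018 simulated. With the controls split r was 0.321, against -0.00391 ± 0.0446 simulated. As each miRNA was drawn independently, this SD leaves out the correlation between miRNAs, and the excess over it is not a test. Pairs of comparisons with no library in common were tested by relabelling (426888 relabellings, 3 pairs). Lactate against control and inhibitor against HIIT + inhibitor had r = 0.299 and rho = 0.436 (SD of r over relabellings 0.129). The fold changes had the same sign in both for 71.5% of miRNAs. For r the exact permutation p was 0.0225 (adjusted 0.0675), so the relation did not pass. The training response without and with the inhibitor had r = 0.161 (exact permutation p = 0.125, adjusted 0.188), and the inhibitor response without and with training r = 0.104 (exact permutation p = 0.326, adjusted 0.326).

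Fold changes followed the GC content of the hairpin arm to different extents, for 460 of the 481 miRNAs. Across miRNAs rho was 0.34 in lactate against control, 0.20 in HIIT against control, 0.21 in inhibitor against control and -0.03 in HIIT + inhibitor against control. It was -0.23 in HIIT + inhibitor against HIIT, -0.18 in HIIT + inhibitor against inhibitor, 0.16 in lactate against HIIT and -0.32 in the interaction.

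Some miRNAs were listed at 0 in libraries where many counts were expected. miR-3473a was at 0 in 23 libraries and held 44 to 167 counts in the other 6, and miR-129-5p was at 0 in 10 and held 60 to 246 counts in 19. Both were chosen after their values were seen. The mean number of such zeros per library was 5 ± 0.71 in control, 4.5 ± 1.97 with lactate, 4.67 ± 1.97 with HIIT, 5.17 ± 2.32 with the inhibitor and 6 ± 3.22 with HIIT + inhibitor.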
